A study of Homo sapiens with 6 samples.

How the data were processed

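Poly(A)-selected RNA was sequenced from Huh7 cells, a human hepatoma line, carrying an empty vector or stably overexpressing CRABP1 or CRABP2. CRABP1 and CRABP2 are small cytosolic proteins that bind retinoic acid. There were 6 libraries in 3 groups of 2. The libraries were made with the KAPA mRNA HyperPrep kit from total RNA, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

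The authors deposited a table of estimated counts, that is, read counts per gene that need not be whole. The submitters' processing notes name STAR 2.4.1, Partek 6 and the hg38 build, with no role or order. The gene annotation, the strand setting and the way reads shared between genes were divided are not given in the sources used here. Fractions occurred in 32.8% of the 56269 genes in the file, as happens when reads that match several genes or isoforms are divided. Values of close paralogs and of overlapping or antisense genes are therefore uncertain. Totals ranged from 32750448 to 44278394 estimated counts per library. At this depth a count of 3 in a library corresponds to 0.0687 to 0.0908 CPM (counts scaled to a common library total), and intervals and floors cover counting error only.

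Estimated counts were rounded to whole numbers, and the analysis fixed before the data were examined, which had assumed plain counts, was otherwise kept. In R 4.3.3, edgeR 4.0.16 filtered genes with filterByExpr by group, which left 16771 genes. Libraries were scaled by TMM, and a group-means model on all 6 libraries was fitted by quasi-likelihood with robust moderation, which left 3 residual degrees of freedom. The model gave each comparison's log2 fold change, its standard error (SE), and a two-sided p with Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p under 0.05 with no fold minimum. CPM values are TMM-scaled, and means are given with the SD over 2 libraries. An exact permutation of 2 libraries against 2 cannot give a p below 0.333, so the tests rest on the spread pooled over genes and groups.

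Before the data were examined, 42 gene lists were written down. The 41 with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists. An estimated correlation was an alternative. Members of a list were also adjusted over the list alone.

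Genes named in the text were chosen by a rule set before the data were examined. It names CRABP1 and CRABP2 always, and up to 10 genes per direction with the largest changes among the called genes, with a characterised symbol, a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. It also names up to 4 called members of each list described, or its 2 most abundant members where none was called, and up to 5 genes per direction changed in both lines. Mitochondrially encoded genes were left out when the largest changes were chosen, which the rule did not state. Other list members and uncalled genes in the text were chosen after the values were seen. Because edgeR called few genes, the same rule was applied to the calls of DESeq2 1.42.0 (Wald test, its own size factors and independent filtering), and genes named that way were chosen after the values were seen. Coordinates are from GENCODE release 29 on GRCh38 (hg38), matched by symbol. Of the tested symbols, 14384 were found there.

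The alternatives were DESeq2 size factors or total counts in place of TMM, other filters, DESeq2 or limma-voom in place of edgeR, fits on 4 libraries, the replicate number as a block, a fold minimum, the older quasi-likelihood method, and each library left out in turn. Unrounded counts, moderation that was not robust, and lists without the 2 transgenes were added after the data were seen. Chance agreement of the 2 lines through their shared controls was estimated from 50 simulated data sets with no group effect. The edgeR and camera steps were tested on simulated counts in which 100 genes were changed by a log2 of 1 and 100 by a log2 of 2. The list of cholesterol biosynthesis genes was also raised by a log2 of 0.5. For CRABP1 against empty vector the test recovered 87% of genes changed by a log2 of 1 and 98% of those changed by a log2 of 2, among 16529 simulated genes, with 29 false calls among 232. For CRABP2 against empty vector it recovered 88% and 99% among 16522 genes, with 22 false calls among 227. For CRABP2 against CRABP1 it recovered 91% and 100% among 16516 genes, with 23 false calls among 233. In each comparison the false share was above that set by the threshold. The changed genes were drawn only above a minimum mean expression, and every group was given the same spread. The wider spread of the real empty vector libraries is thus not in these shares. A low number of calls in the real data is therefore no measure of how few genes changed. Camera found the raised list upward in every comparison (adjusted p at most 3.41e-27), with 0 other lists past the threshold. The simulated counts were drawn independently for each gene, so they could not test the preset correlation.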

Results

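RNA was profiled in Huh7 hepatoma cells carrying an empty vector and in Huh7 lines stably overexpressing cellular retinoic acid binding protein 1 or 2 (CRABP1, CRABP2), with 2 libraries per group. The titles and design of the series pose the question of how the expression profile differs between cells with either protein. The labels give no treatment. The libraries held 37215625 and 37287977 estimated counts for empty vector, 44278394 and 37154585 for CRABP1, and 32750448 and 38706471 for CRABP2. The most abundant transcript in both empty vector libraries was that of the fetal liver protein AFP, at 1.99% and 2.32% of counts. The replicates differed by more than sampling noise in every group. The SD of the log2 difference between replicates, over genes with a mean of at least 5 CPM, was 0.255 for empty vector, 0.154 for CRABP1 and 0.113 for CRABP2.

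Each transgene was expressed in its own line. The CRABP1 gene (ENSG00000166426.7) lies on chromosome 15 at 78340324 to 78348230 on the plus strand. Its transcript reached 11.5 and 11 CPM in the CRABP1 line (504 and 406 rounded counts), against 1 and 0 counts in the empty vector libraries. The ratio of the CRABP1 line to empty vector was 839, with an exact binomial 95% interval of 150 to 33157 (edgeR adjusted p = 3.13e-05). The CRABP2 line had 0 counts of CRABP1 in both libraries, so CRABP1 was at least 271-fold lower there than in the CRABP1 line, at a floor of 3 counts over the group. The CRABP2 gene (ENSG00000143320.8) lies on chromosome 1 at 156699606 to 156705816 on the minus strand. Its transcript reached 13 and 13.5 CPM in the CRABP2 line, against 0.0270 and 0.107 CPM in empty vector and 0.0916 and 0.108 CPM in the CRABP1 line. By edgeR's quasi-likelihood test, CRABP2 was higher than in empty vector by a log2 fold change of 7.55 ± 0.29 (SE, adjusted p = 3.40e-05). It was higher than in the CRABP1 line by 7.02 ± 0.26 (edgeR adjusted p = 1.60e-05). These calls held in every alternative that could test them. No library showed the transgene of another group at the level of its line.

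**Figure D1:**
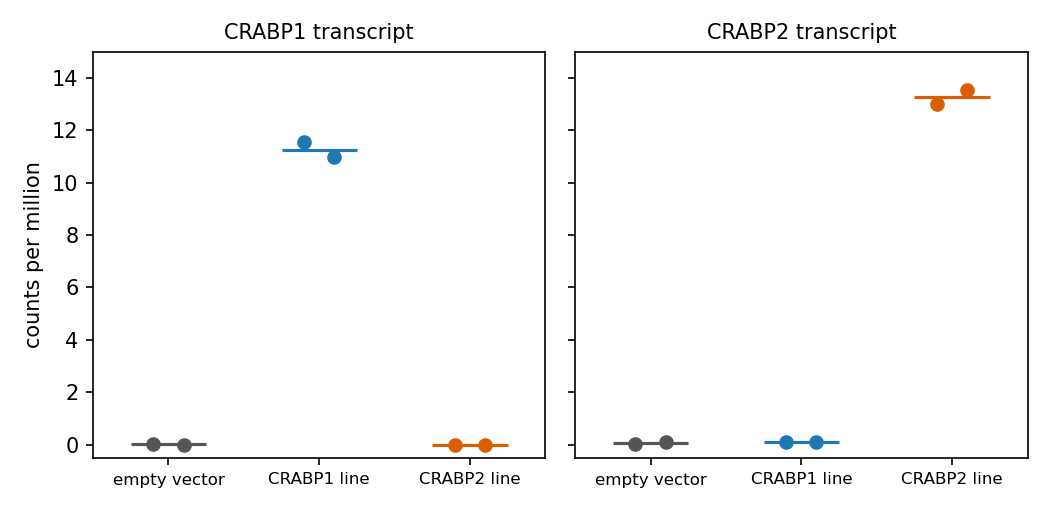
Transcript levels of CRABP1 (left) and CRABP2 (right) in CPM, linear axis. Each point is 1 library and each bar the mean of 2 libraries; CRABP1 reached 11.5 and 11 CPM in its line and CRABP2 13 and 13.5 CPM in its line, and both lay near 0 elsewhere.

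In the CRABP1 line, the clearest change beside the transgene was a fall of AKR1B10, an aldo-keto reductase expressed in many hepatomas. AKR1B10 averaged 211 ± 2.71 CPM (SD, n = 2) in empty vector and 104 ± 5.13 CPM in the CRABP1 line, a log2 fold change of -1.02 ± 0.07 (SE, edgeR adjusted p = 0.00355). ELMO1, a regulator of Rac signalling and cell migration, rose from 1.64 ± 0.0296 to 5.34 ± 0.427 CPM (1.70 ± 0.17 on the log2 scale, edgeR adjusted p = 0.0259). FSCN1, which encodes the actin-bundling protein fascin, rose from 18.6 ± 1.14 to 34.2 ± 1.36 CPM (0.88 ± 0.09, edgeR adjusted p = 0.0259). HK1, encoding hexokinase of glycolysis, fell from 7.74 ± 1.29 to 2.70 ± 0.265 CPM (-1.51 ± 0.17, edgeR adjusted p = 0.0497). The uncharacterised RP11-462L8.1 rose by 2.01 ± 0.22 to 3.59 ± 0.311 CPM (edgeR adjusted p = 0.0484). It was singled out after its values were seen. These genes and CRABP1 made up the 6 calls among 16771 genes, 4 higher and 2 lower, and 1427 genes had an unadjusted p under 0.05. The number of calls was 1003 without empty vector replicate 1, 95 without empty vector replicate 2, 1 without either CRABP1 library and 2 without either CRABP2 library. AKR1B10 was past the threshold in 17 of 19 alternative fits, with a log2 fold change between -1.07 and -0.97. It was lost without CRABP1 replicate 1 (edgeR adjusted p = 0.168) and without CRABP1 replicate 2 (0.0985). Without CRABP1 replicates 1 and 2 and CRABP2 replicates 1 and 2, each left out alone, the edgeR adjusted p became 0.436, 0.532, 0.0851 and 0.0843 for ELMO1, 0.666, 0.532, 0.0954 and 0.0961 for FSCN1 and 0.746, 0.610, 0.105 and 0.106 for HK1. RP11-462L8.1 was likewise lost without each of these 4 libraries, with an edgeR adjusted p up to 0.656. ELMO1 and FSCN1 were each past the threshold in 13 of 19 alternative fits, RP11-462L8.1 in 9 and HK1 in 8, HK1 being lost also with total counts, the CPM filter and limma-voom.

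AKR1B10 (ENSG00000198074.9) lies on chromosome 7 at 134527592 to 134541408, plus strand. Its close paralog AKR1B15 was at 1.12 ± 0.0247 CPM in empty vector, so reads divided between these genes leave AKR1B10 dominant. ELMO1 (ENSG00000155849.15) spans 36854361 to 37449249 on chromosome 7, minus strand, FSCN1 (ENSG00000075618.17) lies at 5592823 to 5606655 on chromosome 7, plus strand, and HK1 (ENSG00000156515.23) at 69269984 to 69401884 on chromosome 10, plus strand. Antisense or overlapping transcripts cannot be separated from these genes because the strand setting was not stated.

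DESeq2 called 104 genes between the CRABP1 line and empty vector, 53 higher and 51 lower, all of them with an unadjusted edgeR p under 0.05 and the same direction. The genes it adds were named after the values were seen. Among the lower genes, GC, the vitamin D binding protein, went from 559 ± 115 to 293 ± 34.8 CPM (DESeq2 log2 fold change -0.92 ± 0.13, adjusted p = 1.65e-08). Coagulation factor gene F12 went from 21.4 ± 4.76 to 10.9 ± 1.28 CPM, LBP (lipopolysaccharide binding protein) from 10.4 ± 3.81 to 4.70 ± 0.121 CPM, and A1BG from 5.05 ± 1.5 to 2.05 ± 0.0800 CPM. The hexokinase-like gene HKDC1, the kynureninase gene KYNU, ALS2CL and the sugar transporter gene SLC5A9 were also lower, with DESeq2 log2 fold changes of -0.96, -0.95, -0.99 and -0.86. The prion protein gene PRNP, LFNG (a glycosyltransferase that modifies Notch), RNF144A, SLFN13, TMCC3 and the tetraspanin gene TSPAN12 were higher. Their DESeq2 log2 fold changes lay between 0.81 for TMCC3 and 1.17 for LFNG. By edgeR none of these genes passed, with adjusted p from 0.0788 for LFNG to 0.273 for ALS2CL. HKDC1 ends at 69267559 on chromosome 10, plus strand, shortly before the start of HK1 at 69269984 on the same strand. Whether the falls of HKDC1 and HK1 are separate changes was not tested.

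Of the 41 gene lists tested, 15 passed at the preset correlation in the CRABP1 line, 10 up and 5 down, and 0 passed with an estimated correlation. The list of NRF2 and oxidative stress genes was lower (median log2 fold change -0.12, 24 of 29 members negative, camera adjusted p = 9.63e-08, and adjusted p = 0.472 with an estimated correlation). In it 1 member fell over all genes tested, AKR1B10, and 4 fell adjusted over the list alone. The others of these 4 were ABCC3 (-0.65 ± 0.11), AKR1C1 (-0.55 ± 0.10) and ABCC2 (-0.49 ± 0.10). ABCC2 and ABCC3 encode organic anion exporters. AKR1C1 has near-identical paralogs, so its value is uncertain. The classical NRF2 target NQO1 had a log2 fold change of -0.07 ± 0.11. Epithelial junction and keratin genes were higher (median 0.15, 21 of 25 positive, camera adjusted p = 6.60e-05, and adjusted p = 0.504 with an estimated correlation). EPCAM, an epithelial adhesion molecule, was the member with the smallest p, at 0.66 ± 0.09, and the 1 that rose adjusted over the list alone, while the abundant keratin genes KRT8 (0.19 ± 0.21) and KRT18 (0.19 ± 0.22) did not pass. Hypoxia and glycolysis genes were higher (median 0.17, 23 of 30 positive, camera adjusted p = 8.67e-04, and adjusted p = 0.472 with an estimated correlation), although HK1 fell. GAPDH had 0.33 ± 0.08 and TPI1 0.29 ± 0.07, and adjusted over the list alone 2 members rose and 1 fell.

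Acute phase genes were lower in the CRABP1 line (median -0.16, 16 of 24 negative, camera adjusted p = 8.33e-04, and adjusted p = 0.472 with an estimated correlation). No member passed over all genes tested. Adjusted over the list alone 10 fell and 3 rose. SAA1 (-0.96 ± 0.22) and SAA2 (-1.05 ± 0.20), which are near-identical copies, were among the former, and the fibrinogen chain genes FGA (0.37 ± 0.08), FGB (0.45 ± 0.14) and FGG (0.36 ± 0.08) were the latter. The NRF2, epithelial, hypoxia and acute phase lists stayed past the threshold without any 1 library. Cell cycle lists did not, and none of their members passed over all genes tested or adjusted over the list alone, MKI67 lying at 0.07 ± 0.13, TOP2A at 0.09 ± 0.09, MCM7 at 0.13 ± 0.10 and RRM2 at 0.06 ± 0.14. The G2 and mitosis list was higher than empty vector (median 0.09, camera adjusted p = 0.0276, and adjusted p = 0.842 with an estimated correlation). Without empty vector replicate 2 it was lower (adjusted p = 0.00630), and without CRABP1 replicate 1 it did not pass (adjusted p = 0.691). The S phase list likewise went from higher (median 0.10, camera adjusted p = 0.0192, and adjusted p = 0.842 with an estimated correlation) to lower without empty vector replicate 2 (adjusted p = 0.0541), and it was lost without CRABP1 replicate 1 (adjusted p = 0.400). Hepatocyte secreted plasma proteins, with ALB at -0.29 ± 0.12 and SERPINA1 at -0.03 ± 0.13, were lower with a median of -0.12 (camera adjusted p = 0.0192, and adjusted p = 0.782 with an estimated correlation). That call was lost without empty vector replicate 2 (adjusted p = 0.787) and without CRABP1 replicate 1 (adjusted p = 0.691). Of its members 3 rose and 5 fell adjusted over the list alone, and none passed over all genes tested. In the mean log2 CPM per library, the empty vector libraries lay on either side of all CRABP1 and CRABP2 libraries for the S phase list (6.15 and 5.88).

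**Figure D2:**
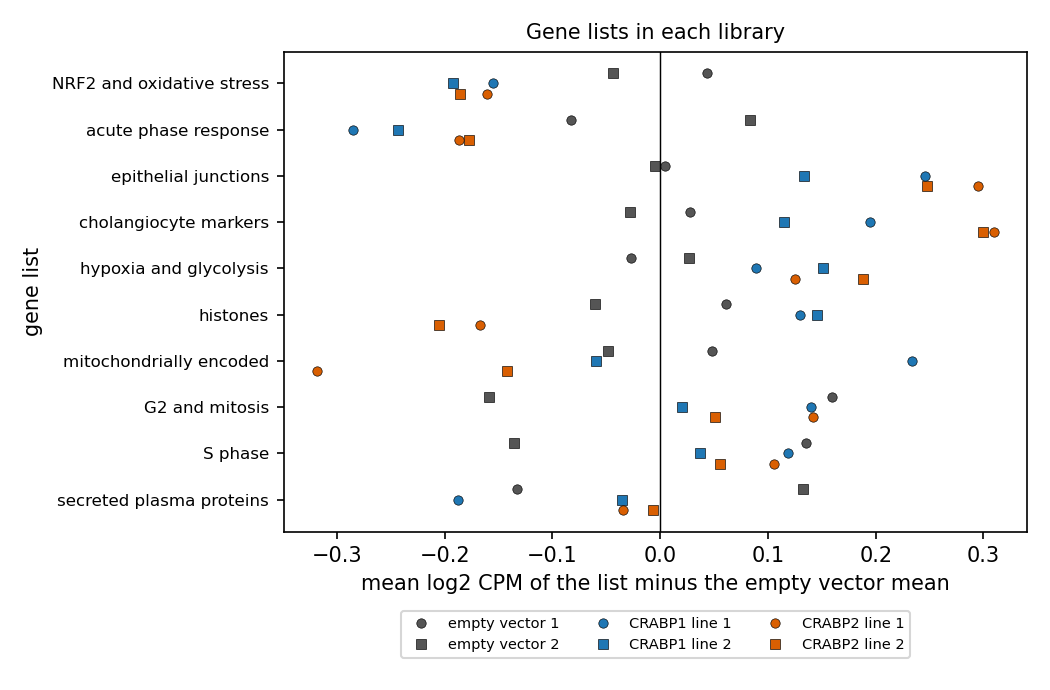
Mean log2 CPM of 10 gene lists in each of the 6 libraries, minus the mean of the empty vector libraries; circles are replicate 1 and squares replicate 2. NRF2 and acute phase lists lay below both empty vector libraries in all 4 CRABP libraries and epithelial, cholangiocyte and hypoxia lists above, whereas for the S phase list the empty vector libraries lay on either side, at 6.15 and 5.88.

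In the CRABP2 line, edgeR called 1 gene against empty vector, CRABP2 itself, while 1213 genes had an unadjusted p under 0.05. DESeq2 called 68 genes, 48 higher and 20 lower, and the genes described here were named from these calls after the values were seen. The liver-intestine cadherin gene CDH17 was higher, at 11.7 ± 4.20 CPM (SD, n = 2) in empty vector and 36.9 ± 3.95 CPM in the CRABP2 line (DESeq2 log2 fold change 1.67 ± 0.20, adjusted p = 1.35e-13, edgeR adjusted p = 0.0577). The carboxylesterase gene CES1 went from 2.10 ± 0.522 to 7.62 ± 0.234 CPM (1.87 ± 0.27, DESeq2 adjusted p = 5.12e-08) and the transcriptional repressor gene PRDM1 from 2.07 ± 0.408 to 5.42 ± 0.00575 CPM (1.40 ± 0.29, DESeq2 adjusted p = 0.00119). TMCC3, SLFN13, TSPAN12, SNCAIP and TSPAN5 were higher too, with DESeq2 log2 fold changes from 0.90 for TSPAN5 to 1.04 for TMCC3. Among the lower genes, RANBP3L had -0.94 ± 0.18, GC -0.80 ± 0.13, RELN (the secreted glycoprotein reelin) -0.79 ± 0.17, GFRA1 (a GDNF receptor) -0.77 ± 0.15 and WWC3 -0.72 ± 0.14. F12, LURAP1L, the nuclear noncoding RNA NEAT1, CCNY and ASGR1 (the hepatic asialoglycoprotein receptor) lay between -0.70 for F12 and -0.61 for ASGR1. The mitochondrially encoded MT-RNR1 was also called lower, at -0.68 ± 0.11 (DESeq2 adjusted p = 8.09e-07, edgeR adjusted p = 0.101). In the CRABP1 line DESeq2 called MT-RNR1 lower too, at -0.44 ± 0.11 (adjusted p = 0.0130, edgeR adjusted p = 0.265). There 12 of 13 listed mitochondrially encoded transcripts, which do not include MT-RNR1, had positive log2 fold changes. The edgeR count was 444 without empty vector replicate 1, 137 without empty vector replicate 2, and 1 without any other library.

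Of 41 lists, 15 passed at the preset correlation in the CRABP2 line, 9 up and 6 down, and 0 with an estimated correlation. NRF2 and oxidative stress genes were lower (median -0.19, 25 of 29 negative, camera adjusted p = 3.96e-09, and adjusted p = 0.328 with an estimated correlation). In it 4 members fell adjusted over the list alone, among them AKR1B10 (-0.53 ± 0.07) and AKR1C1 (-0.50 ± 0.10). The abundant ferritin genes had -0.01 ± 0.09 (FTH1) and -0.25 ± 0.09 (FTL). Epithelial junction and keratin genes were higher (median 0.15, 22 of 25 positive, camera adjusted p = 9.25e-09, and adjusted p = 0.328 with an estimated correlation), and 4 rose adjusted over the list alone. EPCAM had 0.79 ± 0.09, CDH17 1.66 ± 0.20 and KRT19 0.73 ± 0.20. KRT8 had 0.20 ± 0.21 and KRT18 0.19 ± 0.22. The cholangiocyte markers, which share EPCAM and KRT19 with that list, were higher in 10 of 11 members (median 0.31, camera adjusted p = 5.24e-07, and adjusted p = 0.310 with an estimated correlation), and 3 rose adjusted over the list alone, among them ANXA4 (0.35 ± 0.07), while SOX9 had 0.07 ± 0.07. Hypoxia and glycolysis genes were higher in 24 of 30 members (median 0.14, camera adjusted p = 7.66e-05, and adjusted p = 0.310 with an estimated correlation), with GAPDH at 0.28 ± 0.08 and ENO1 at 0.23 ± 0.12, and 1 member, EGLN3 (1.19 ± 0.23), rose adjusted over the list alone. The mitochondrially encoded transcripts were lower in 13 of 13 members (median -0.24, camera adjusted p = 4.52e-06, and adjusted p = 0.583 with an estimated correlation), with MT-CO1 at -0.18 ± 0.13 and MT-ND4 at -0.27 ± 0.13, and no member passed either way. These 5 lists passed without any 1 library. No member of the 5 passed over all genes tested. The G2 and mitosis list passed upward (median 0.09, camera adjusted p = 0.00581, and adjusted p = 0.871 with an estimated correlation). It turned downward without empty vector replicate 2 (adjusted p = 0.0157) and was lost without CRABP2 replicate 1 (adjusted p = 0.282). MKI67 had 0.14 ± 0.13 and TOP2A 0.09 ± 0.09. In that list 1 member rose adjusted over the list alone.

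Among retinoic acid target genes, edgeR called CRABP2 alone, in its own line. In the CRABP1 line the list of 24 tested targets had a median log2 fold change of -0.03 (camera adjusted p = 0.346). In that line no target passed by edgeR over all genes tested, and 2 fell adjusted over the list alone, among them the transglutaminase gene TGM2 (-0.39 ± 0.08). DESeq2 gave TGM2 an adjusted p of 0.0178. In the CRABP2 line the list passed upward (camera adjusted p = 0.00516, and adjusted p = 0.328 with an estimated correlation), but CRABP2 is itself a member and was the 1 member that rose, over all genes tested and adjusted over the list alone. The list median was 0.01, and with both transgenes left out the adjusted p was 0.915. It also did not pass without empty vector replicate 1 (adjusted p = 0.203). RARB, a receptor gene induced by retinoic acid, had -0.45 ± 0.18 in the CRABP1 line and -0.11 ± 0.18 in the CRABP2 line, and DHRS3, a retinal reductase gene, had 0.32 ± 0.10 and 0.23 ± 0.10. Neither RARB nor DHRS3 passed by edgeR. The list of retinoid transport and metabolism genes had 1 member that rose in each line, the transgene. In the CRABP1 line it did not pass (camera adjusted p = 0.121). In the CRABP2 line it passed upward (camera adjusted p = 0.00516, and adjusted p = 0.515 with an estimated correlation), with a mean of 0.25 but a median just below 0. Adjusted over the list alone RBP2 (1.39 ± 0.23), a retinol binding protein gene, rose with CRABP2. That call was lost with the transgenes left out (adjusted p = 0.871), without empty vector replicate 1 (0.252) and without CRABP2 replicate 2 (0.147). Genes of PPAR signalling and fatty acid oxidation had a median of -0.03 in both lines and did not pass (camera adjusted p = 0.430 and 0.514).

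Changes against empty vector resembled each other in the 2 lines as long as both used the same controls. Over 10715 genes with a mean of at least 5 CPM, the log2 changes correlated with r = 0.806 with shared controls. With a different single control library for each line, r was 0.125 in 1 assignment and -0.00658 in the other. A single control also carries more noise than the mean of 2, which lowers r. Across 16771 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.590, against 0.504 in simulated groups with no effect that shared the same controls (range 0.487 to 0.527). The covariance was 0.0670 against a simulated 0.0358. edgeR called 0 genes in both lines, and 690 genes had an unadjusted p under 0.05 in both with the same direction, 320 higher and 370 lower, against 175 in the simulation and 52.2 for independent lists. DESeq2 called 38 in both, 22 higher and 16 lower, against a mean of 0.4 over 10 simulations and 0.114 for independent lists. ELMO1 had 1.70 ± 0.17 and 1.55 ± 0.17 by edgeR, with adjusted p of 0.0259 in the CRABP1 line and 0.0508 in the CRABP2 line. TMCC3, TSPAN12 and SLFN13 were other genes with the largest upward change in the weaker of the 2 lines, and GC, WWC3, RANBP3L, GFRA1 and F12 those downward, all by DESeq2 and chosen after the values were seen. WWC3 had -0.68 ± 0.09 and -0.72 ± 0.09. The real empty vector libraries differed more than the other replicates, which the simulation does not hold, so its values are too low a reference. The resemblance may thus come largely from the shared empty vector libraries, and edgeR called 365 genes in both without empty vector replicate 1 and 58 without empty vector replicate 2.

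**Figure D3:**
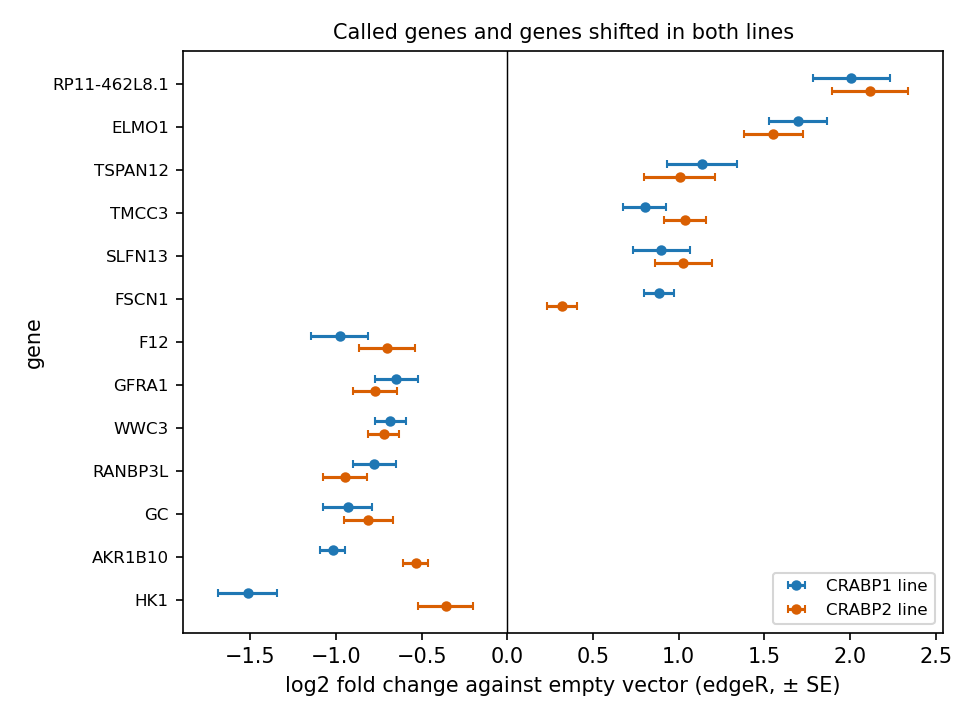
edgeR log2 fold changes with their SE against empty vector in the CRABP1 line and the CRABP2 line for 13 genes, called in the CRABP1 line or changed in both lines by DESeq2. Points right of 0 are higher than in empty vector; ELMO1 lay at 1.70 and 1.55, whereas HK1 lay at -1.51 in the CRABP1 line and -0.36 in the CRABP2 line.

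Compared directly, the 2 lines differed by edgeR in CRABP1 and CRABP2 only, while 413 genes had an unadjusted p under 0.05. DESeq2 called 16 genes, 11 higher and 5 lower in the CRABP2 line, and the genes described here were named from these calls after the values were seen. IPO8, which encodes a nuclear import receptor, averaged 402 ± 14.0 CPM (SD, n = 2) in the CRABP1 line and 277 ± 4.29 CPM in the CRABP2 line (DESeq2 log2 fold change -0.54 ± 0.09, adjusted p = 4.16e-06, edgeR adjusted p = 0.248). FSCN1 (-0.57 ± 0.13), the linker histone gene HIST1H1C (-0.64 ± 0.14) and NTS, the neurotensin gene (-0.54 ± 0.12), were also lower in the CRABP2 line. CDH17 (1.06 ± 0.19), PRDM1 (1.25 ± 0.29), HK1 (1.16 ± 0.24), PARM1 (1.04 ± 0.23) and COL12A1, a collagen gene (0.80 ± 0.17), were higher, as were SPX, AGR2, SLC7A7 and AKR1B10, whose DESeq2 log2 fold changes lay between 0.48 for AKR1B10 and 0.67 for SPX. The edgeR count was 25 without empty vector replicate 1, 27 without empty vector replicate 2, and 2 without any other library.

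Of 41 lists, 9 passed at the preset correlation between the lines, 5 up and 4 down in the CRABP2 line, and 0 with an estimated correlation. The count was 17 without either empty vector library, 15 without CRABP1 replicate 1 and 16 without CRABP1 replicate 2. Replication-dependent histone transcripts, listed as RNA without poly(A) tails, were lower in the CRABP2 line in 25 of 28 members. The median was -0.49 (camera adjusted p = 1.21e-20, and adjusted p = 0.179 with an estimated correlation). Whether the reads came from forms with or without tails was not tested. Adjusted over the list alone 8 fell, among them HIST1H2BD (-0.73 ± 0.15), HIST1H1C (-0.64 ± 0.13) and HIST1H2BK (-0.52 ± 0.16), while HIST1H2AC had -0.50 ± 0.18. Mitochondrially encoded transcripts were lower in 13 of 13 members (median -0.35, camera adjusted p = 1.21e-20, and adjusted p = 0.444 with an estimated correlation), and 8 fell adjusted over the list alone, among them MT-CO1 (-0.37 ± 0.13) and MT-ND4 (-0.35 ± 0.13). All mitochondrially encoded genes in the file, including MT-RNR1, which is not in the list, made up 5.13% and 4.31% of counts in the CRABP1 libraries. Their share was 3.64% and 4.08% in the CRABP2 libraries and 4.62% and 4.45% in empty vector. Drug metabolism genes were higher in the CRABP2 line in 25 of 31 members (median 0.16, camera adjusted p = 3.21e-07, and adjusted p = 0.476 with an estimated correlation). Adjusted over the list alone 4 rose, among them CES1 (0.95 ± 0.19) and AOX1 (0.68 ± 0.16), while AHR had 0.04 ± 0.10 and UGT2B4 0.05 ± 0.14. These 3 lists passed without any 1 library, and no member passed over all genes tested by edgeR. The retinoic acid target list passed upward (camera adjusted p = 3.85e-09, and adjusted p = 0.217 with an estimated correlation). Its 1 member that rose, over all genes tested and adjusted over the list alone, was CRABP2. The list had a median of 0.08, and the adjusted p was 0.122 with both transgenes left out.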

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

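Unrounded counts, moderation that was not robust and lists without the transgenes were chosen after seeing the data. The 4 transgene calls held in all alternatives that could test them. In the order CRABP1 against empty vector, CRABP2 against empty vector and CRABP2 against CRABP1, edgeR's 6, 1 and 2 calls became 104, 68 and 16 with DESeq2, and 21, 22 and 2 with no filter on low counts. CRABP1 against empty vector had 4 calls with total counts, 4 with the CPM filter, 3 with limma-voom, 2 with the 4 libraries of the comparison and 3, 0 and 0 with the transgenes left out. This setting removes CRABP1 from the first count, and HK1 (edgeR adjusted p = 0.0597) and RP11-462L8.1 also no longer passed in it. At these 0 calls, edgeR gave 1212 and 411 genes with an unadjusted p under 0.05. DESeq2 was fitted only with the transgenes kept. Its 68 and 16 calls both include CRABP2, and the 16 also include CRABP1. CRABP2 against empty vector had 8 with DESeq2 size factors, and CRABP2 against CRABP1 had 23 with its 4 libraries only. With moderation not robust CRABP1 against empty vector had 4. Leaving out single libraries gave ranges of 1 to 1003, 1 to 444 and 2 to 27. The high ends came without an empty vector library, a fit in which the difference between the control libraries no longer enters the spread; the cause of the other shifts was not tested.

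The replicate block gave 307, 219 and 20 calls, 119 genes in both lines and 16 lists between the lines. Deviations of same-numbered libraries correlated at 0.248 and 0.145 for empty vector with each line and at 0.0896 between the lines, all positive. The number was left out of the model beforehand because the labels do not say what it marks. Whether it marks a pairing therefore cannot be told.

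Genes changed in both lines were 0 in the fit, 2 with DESeq2 size factors, 8 with no filter on low counts, 38 with DESeq2 and 0 to 365 without single libraries. Gene lists past the threshold, 15, 15 and 9, fell to 0, 0 and 0 with the estimated correlation. Without single libraries they ranged 10 to 21, 11 to 22 and 7 to 17. Some lists turned direction, both lists that had passed before and lists that had not. Each is given with camera's adjusted p over all 6 libraries, that in the setting and, in brackets, the lowest to highest over the fits without 1 library. Without empty vector replicate 2 these were, in CRABP1 against empty vector, secreted proteins 0.0192 and 0.787 (8.78e-07 to 0.787), G2 and mitosis 0.0276 and 0.00630 (3.39e-10 to 0.691), S phase 0.0192 and 0.0541 (2.15e-09 to 0.400), TGF-beta and YAP targets 0.0483 and 0.821 (1.77e-04 to 0.906), heat shock 0.168 and 0.0127 (1.65e-07 to 0.906), and in CRABP2 against empty vector G2 and mitosis 0.00581 and 0.0157 (5.88e-13 to 0.282), S phase 0.0128 and 0.0275 (1.63e-10 to 0.226), the unfolded protein response 0.694 and 0.00796 (0.00796 to 0.823), heat shock 0.314 and 0.00383 (9.25e-08 to 0.946). Without CRABP1 replicate 1 they were TGF-beta and YAP targets 0.0483 and 0.906 (1.77e-04 to 0.906), ribosomal proteins 0.471 and 0.0346 (3.64e-04 to 0.559) in CRABP1 against empty vector and nuclear oxidative phosphorylation 0.95 and 0.0203 (0.0135 to 0.959) between the lines. Without CRABP1 replicate 2 they were apolipoproteins 0.95 and 0.0416 (0.0416 to 0.938), ribosomal proteins 0.0612 and 0.0473 (2.84e-09 to 0.330) between the lines. With the transgenes left out, the retinoic acid targets in CRABP2 against empty vector turned, with a camera adjusted p of 0.00516 before and 0.915, since CRABP2 is a member. Over all settings, named genes became stronger in 238 results and weaker in 25, while lists became stronger in 83 and weaker in 88. No named gene turned direction where it passed in either of the fits compared. Turns of genes that passed in neither fit were not counted. Depth limits genes near the floor of 0.0687 to 0.0908 CPM.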

Other observations

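The tests of mislabelling, of depth, of culture state, of S phase cells and of an unrelated difference of the control culture were chosen only after the result was seen, as was the error used for the shared controls.

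The 2 empty vector libraries differed more than other replicates, and growth and liver genes were among those that differed. In replicate 2, G2 and mitosis genes had a median log2 difference of -0.32 from replicate 1, S phase genes -0.27, heat shock genes -0.37 and TGF-beta and YAP targets -0.20. Each median lay below all 10000 random lists of the same size matched on expression. Secreted plasma proteins (0.33), apolipoproteins (0.31) and hepatocyte metabolism genes (0.32) lay above all of them. Over genes with a mean of at least 5 CPM, the largest differences were at the clone-named CH507-513H4.3, CH507-513H4.4 and CH507-513H4.6. All of them had identical values, 658 CPM in replicate 1 and 2436 CPM in replicate 2, so they cannot be counted as separate changes. Whether the same reads were divided among them was not tested, nor was the cause of the difference. Other genes with large differences included ANKRD1, from 70.8 to 24.9 CPM, and CYR61, from 49.3 to 24.9 CPM. TXNIP went from 17.4 to 60.7 CPM and ARG1 from 9.18 to 18.5 CPM. These gene values describe 2 libraries, with no replicate check. The mean log2 CPM of each list above moved the same way, by less, between the replicates of CRABP1 and of CRABP2. From replicate 1 to replicate 2, G2 and mitosis went from 7.086 to 6.9662 in CRABP1 and from 7.088 to 6.9974 in CRABP2. Heat shock went from 7.5485 to 7.4094 and 7.5099 to 7.4083, and secreted proteins from 5.8641 to 6.0163 and 6.017 to 6.0452. The shift of these lists thus followed the replicate number in every group.

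A candidate explanation is another culture state of replicate 2, such as denser or more differentiated cells. The secreted protein list, at percentile 100 of random lists, gave rise to this idea and is no test of it. The lists moved the same way between the replicates of every group, so the difference may not be particular to the controls. With no record of density, no stated meaning of the replicate number and 1 empty vector library on each side, culture state cannot be told apart from other causes. A CRABP library among the controls is argued against by the transgenes, at most 0.107 CPM there against 11 CPM in the lowest library of their lines. Depth is argued against by totals 0.194% apart, closer than the CRABP1 pair at 17.5%. GC content and transcript length took 2.45% of the variance of the difference, and the SD after removing them was 0.248, above the 0.145 of the CRABP1 pair.

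Much of the shift shared by both lines may come from the same controls. Over 10715 genes with a mean of at least 5 CPM, the covariance of the 2 lines' log2 changes was 0.0183. The variance of the empty vector mean was 0.0162. With a different control library for each line the correlation was 0.125 or -0.00658, which restates the same values and is no separate test. The excess of 0.00208 passes the bound set beforehand when its error is taken over genes (5.67e-04). That bound was wrong, because genes are not independent and the 2 control libraries leave 1 degree of freedom (standard error 0.0229), so chance in the controls and a common change cannot be told apart. GC content and length took 1.74% of the variance of the mean change, which argues against them as the cause. With 1 control line and no parental line, a difference of the control culture unrelated to either protein and an effect of both proteins cannot be told apart.

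Histone transcripts were lower in both CRABP2 libraries (mean log2 CPM 1.32 and 1.28) than in both CRABP1 libraries (1.61 and 1.63), with empty vector at 1.55 and 1.42. Carry-over of RNA without tails was examined in 11 other transcripts listed as such, of which 10 were not lower in CRABP2. Their median log2 change was 0.292, with a bootstrap interval of 0.0645 to 0.558 over genes. These values met the bound set beforehand against carry-over. They cannot decide, because the interval leaves out the spread between libraries and most of these transcripts lay under 1 CPM. TERC, for example, lay at 0.135 CPM in CRABP1 and 0.151 CPM in CRABP2. Whether the histone reads came from RNA without tails is also not known. Removing GC content and length left the 14 histones with at least 1 CPM at a median of -0.559, so GC content and length are argued against. A smaller share of cells in S phase may remain, since the S phase list differed by 0.00308 with a 95% interval of -0.20 to 0.21, too wide with 2 libraries per group, and histone levels unlinked to the cycle were not tested.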
